A study of Mus musculus with 4 samples.

How the data were processed

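RNA was measured by sequencing in ventral and dorsal prostate lobes of 4 FVB mice, 2 wild type (mice 27 and 28) and 2 homozygous for a TMPRSS2:ERG transgene (mice 26 and 29). Groups were taken from the labels, which give each library its own mouse, and no mouse is shared between genotypes. Per the labels' protocols, RNA was extracted with the RNeasy Plus kit and libraries were made with standard Illumina protocols.

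The deposited table gives 1 FPKM value (fragments per kilobase of transcript per 1e6 fragments) per gene and library in 23242 rows. The unit was read from the values, because the headers name libraries without a unit. The submitters' processing notes name TopHat 1.3, Cufflinks 1.3 and genome build mm10. Their roles and settings, the annotation and the use of strand are not given in the sources used here. The table also holds the authors' deposited log2 fold change between genotypes with a p-value and a q-value per gene, per the file headers. The log base was read from the values, and the tool behind that comparison is not given in the sources used here. In 266 rows of the authors' deposited table the fold is rounded to at most 2 decimals. Of the 172 such rows with a positive fold, 171 have a p-value over 0.5, all 89 with a negative fold have one of at most 0.5, and 258 of the 266 have a q-value of 1.

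FPKM values are not counts, so depth cannot be read from them directly. The lowest nonzero values of genes with 1 annotated transcript formed a step that places each library near 45 × 1e6 fragments. This is an estimate, read in bins of 0.2 on the log2 scale. The 4 deposited columns summed to 1.07e+06, 871753, 717164 and 773794 FPKM for mice 27, 28, 26 and 29. A single top value, 99999, occurs in 7 genes and stands far above the next highest of 35610.7, so it was read as a code or upper limit and treated as missing. Without it the columns summed to 471938, 471757, 517166 and 473797 FPKM for mice 27, 28, 26 and 29. Between 7 and 12 cells per library are blank. Starts in the table were raised by 1, since 7244 of the 20887 symbols found in GENCODE for the same build then share its start, against 747 without that step.

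FPKM values were divided by median-of-ratios scaling factors over genes with at least 1 FPKM in each library (0.921, 1.03, 1.01 and 1.04 for mice 27, 28, 26 and 29). Genes with a mean of at least 1 scaled FPKM and no missing value were tested, 11762 in all. Log2(scaled FPKM + 1) was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend, two-sided, Benjamini-Hochberg adjustment, threshold 0.05). Fold changes are on that scale, which understates the change of low genes. The fit has 2 residual degrees of freedom and a prior worth 3.62. On data simulated for the TMPRSS2:ERG homozygote against wild type comparison with 11762 genes, 200 of them changed, 69% of the genes changed by 1 on the log2 scale and 97% of those changed by 2 were recovered, and 5.1% of calls were false. The simulated genes varied independently, with a variance drawn from the fitted prior and equal in both genotypes. In the libraries the median absolute log2 difference was 0.183 between wild types and 0.106 between homozygotes. The simulated 5.1% is therefore not a measure of error among the calls reported below. Erg and Tmprss2 also had an exact permutation test over the 6 arrangements, which cannot give a two-sided p under 0.333.

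The 34 gene lists were fixed before the data were examined, and the 32 with at least 5 tested genes were tested with camera in limma at a preset inter-gene correlation of 0.01, adjusted over lists. The genes named in the text were chosen by a rule also fixed before the data were examined. It takes Erg and Tmprss2, the 12 largest rises and the 12 largest falls among called genes whose groups do not overlap, and the 2 members of each list with the largest moderated statistic (4 for a called list). Any other named gene was chosen after its values were seen.

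Alternatives were unscaled FPKM, quantile normalization, a pseudocount of 0.1, no filter, a minimum mean of 5, no trend, a robust trend, each library left out, leaving out 42 secretory, seminal vesicle or abundant genes, camera with an estimated correlation, fry, and the authors' deposited call. With a library left out, the lone library of its group is assumed to vary like the other group. For the robust trend, lists were tested on the moderated statistics. Count-based tests were not run, because the values are FPKM. Another 3 alternatives and 2 gene lists were added after the data were seen.

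The closing section rests on 11 tests of explanations, of which 3 were written before and 8 after the result they measure was seen. Of the 8, 3 are rewritten versions of earlier criteria, made with the values in view. Both the earlier and the rewritten versions are reported. Another 1, the count of chromosomes, was added because the test of close pairs could not decide. Transcripts of the human ERG cassette were not analysed here.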

Results

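Gene expression was measured by RNA sequencing in ventral and dorsal prostate lobes of FVB mice, with 2 wild-type animals (mice 27 and 28) and 2 animals homozygous for a TMPRSS2:ERG transgene (mice 26 and 29). The transgene places exons of human ERG, an ETS-family transcription factor, in a bacterial artificial chromosome that carries the TMPRSS2 locus. Each library had between 11541 and 11854 genes at 1 FPKM or more, and the step between the lowest values places each near 45 × 1e6 fragments, an estimate. Across the 11762 genes tested, the Pearson correlation across genes was 0.992 between the homozygotes and 0.976 between the wild types. It lay between 0.938 and 0.946 for pairs of different genotype. The median absolute log2 difference separated the genotypes less: it was 0.106 between the homozygotes, 0.183 between the wild types and 0.170 to 0.224 across genotypes, and mouse 27 was nearer to mouse 26 (0.176), and mouse 28 to mouse 29 (0.170), than the wild types to each other. Genes are not independent replicates.

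Mouse Erg and mouse Tmprss2 were read first, as the genes nearest to the construct. Mouse Erg (Entrez 13876, chromosome 16, 95360204 to 95530365, mm10) was at 0.994 ± 0.0974 scaled FPKM (SD, n = 2) in wild type and 1.00 ± 0.170 (SD, n = 2) in homozygotes. The exact permutation test gave p = 1, and the gene lay just under the filter on low values. Mouse Erg therefore does not separate the genotypes, and it checks the labels only in part because the transgene carries human exons. Tmprss2, an androgen-regulated serine protease (Entrez 50528, chromosome 16, 97564682 to 97611195), was at 76.4 ± 3.15 scaled FPKM (SD, n = 2) in wild type and 45.1 ± 3.90 (SD, n = 2) in homozygotes. It fell by 0.75 on the log2 scale (SE 0.118, limma adjusted p = 0.0209), lower in both homozygotes than in both wild types. The exact permutation p was 0.333, the smallest this design allows. The limma call was lost with unscaled FPKM (adjusted p = 0.0597), without mouse 26 (0.228) and without mouse 29 (0.102).

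The comparison of genotypes asks which transcripts differ in prostate lobes that carry the fusion transgene. In homozygotes, transcripts of Spink3 and of 6 seminal vesicle genes were far lower, and Dlk1, Tpsab1, Reg3b, Reg3g and Saa3 were far higher. Of 11762 genes tested with limma, 900 passed an adjusted p of 0.05, of which 547 were higher and 353 lower in homozygotes. Changes of at least 1 on the log2 scale made up 265 of the rises and 155 of the falls. The groups did not overlap in 51.1% of tested genes, where chance gives 33.3%. Without scaling, 73.0% of calls were rises, against 60.8% with it. The number called depended on the libraries: it was 2028 without mouse 27, 1630 without mouse 28, 355 without mouse 26 and 394 without mouse 29. The authors' deposited table holds 2034 genes with a q-value under 0.05, and 828 of the 900 genes were called there in the same direction.

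**Figure D1:**
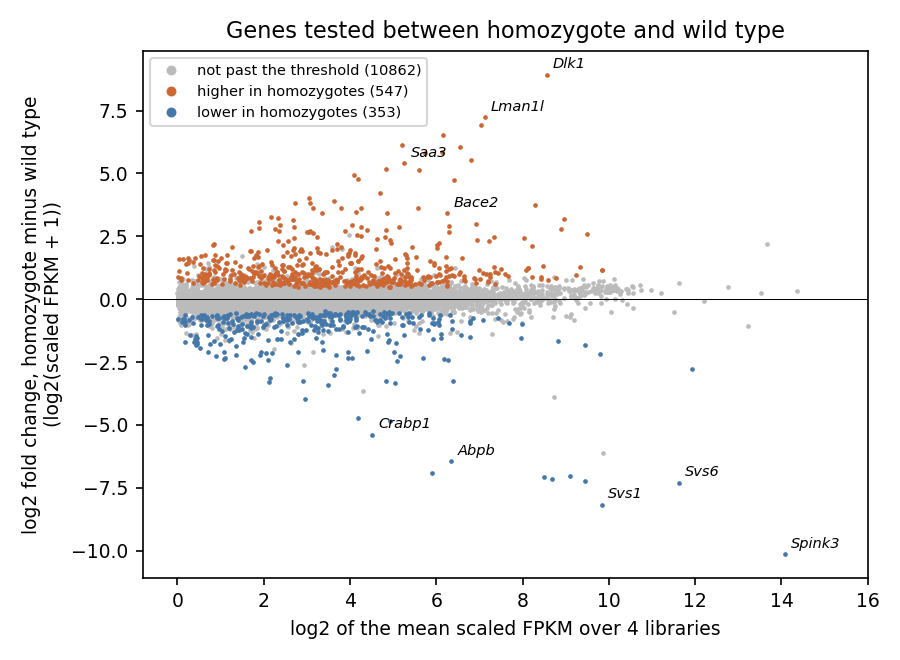
Log2 fold change of each tested gene (homozygote minus wild type, on log2(scaled FPKM + 1)) against the log2 mean scaled FPKM over 4 libraries, 1 point per gene. The 547 called rises lie above 0 and the 353 called falls below it, and Spink3 and Dlk1 lie at the lower and upper ends.

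Among tested genes the largest fall was that of Spink3, a secreted trypsin inhibitor (Entrez 20730, chromosome 18, 43728069 to 43737237), from 34642 ± 5662 scaled FPKM (SD, n = 2) in wild type to 52.9 ± 62.5 (SD, n = 2) in homozygotes (log2 fold change -10.12, SE 1.02, limma adjusted p = 0.00475). The authors' deposited table gives Spink3 a log2 fold of -9.29 with a q-value of 1, 1 of the rows with rounded folds. Next were the seminal vesicle secretory genes Svs1 (-8.16, SE 1.21), Svs6 (-7.29, SE 1.42), Svs3a (-7.22, SE 1.305), Svs3b (-7.16, SE 1.29), Sva (-7.07, SE 1.42) and Spinkl (-7.02, SE 1.48). The wild types differed widely in them: Svs1 was at 3421 scaled FPKM in mouse 27 and 236 in mouse 28, against 3.83 and 1.05 in mice 26 and 29. All 7 of these calls were lost with a robust trend, and all but that of Spink3 without a filter on low values. The calls of Svs6, Sva and Spinkl were also lost without mouse 26, without mouse 29 and with unscaled FPKM. Those of Sva and Spinkl were lost with quantile normalization, and that of Spinkl without a trend and with the code at the top of the scale kept as a value. Abpb (-6.43, SE 0.547), the retinoic acid binding protein gene Crabp1 (-5.38, SE 0.174), the lectin gene Itln1 (-4.83, SE 0.250) and Wfdc3 (-4.72, SE 0.163) also fell. Atp6v1c2, a proton pump subunit gene, was listed at 118 and 113 FPKM in mice 27 and 28 and at 0 in both homozygotes, while the authors' deposited table gives it a log2 fold of -0.59. It overlaps another row of the table. The near-identical genes Sbp and Sbpl could not be tested, because both hold the code at the top of the scale, read as missing, in both wild types. In homozygotes they were at 152 and 5.13 FPKM (Sbp) and at 70.9 and 2.42 FPKM (Sbpl) in mice 26 and 29. The authors' deposited table gives them larger falls than Spink3, a log2 fold of -10.31 (q-value 0.0027) for Sbp and -11.41 (q-value 5.9e-04) for Sbpl. Those folds equal the log2 ratios of group means with the code taken as a value.

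**Figure D2:**
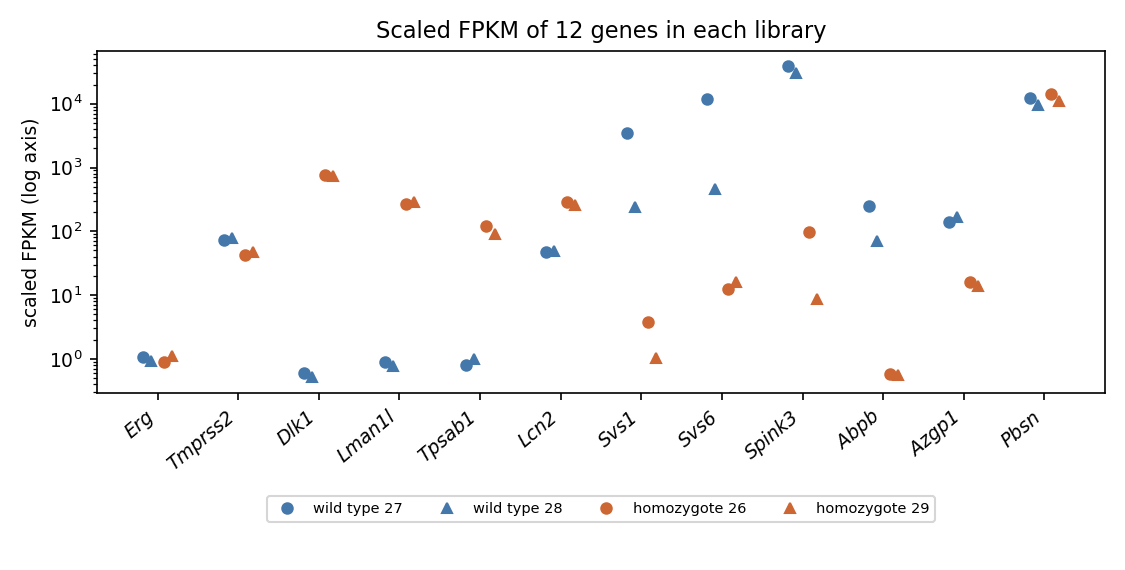
Scaled FPKM (log axis) of 12 genes in each library, with 1 point per mouse and no averaging. Erg lies near 1 in each library, Dlk1 is at 774 and 735 in mice 26 and 29 and under 1 in both wild types, and the wild types differ from each other in Svs1 and Svs6.

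The largest rise was that of Dlk1, an imprinted gene for a Notch-related membrane protein (Entrez 13386, chromosome 12, 109452823 to 109463336), from 0.554 ± 0.0591 scaled FPKM (SD, n = 2) to 755 ± 27.2 (SD, n = 2), a log2 fold change of 8.93 (SE 0.103, limma adjusted p = 6.29e-06). Lman1l rose by 7.25 (SE 0.103) and the serine protease inhibitor gene Serpinb11 by 6.91 (SE 0.145). Otos (6.11, SE 0.119), Abpd (6.04, SE 0.351), the mast cell tryptase gene Tpsab1 (5.81, SE 0.158), the acute-phase gene Saa3 (5.40, SE 0.415) and the imprinted noncoding RNA Rian (5.17, SE 0.171) were also among the largest rises. So were 2 genes of predicted names, Gm5325 (6.53) and Gm5326 (5.14), both on chromosome 7 with Abpd. The antimicrobial lectin genes Reg3b (5.86, SE 0.653) and Reg3g (5.54, SE 0.866) varied between the homozygotes: Reg3b was at 224 and 54.2 scaled FPKM in mice 26 and 29. Both Reg3 calls were lost with a robust trend, and that of Reg3g also without a filter.

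Of 32 gene lists tested, 18 passed camera at the preset correlation, 6 upward and 12 downward. With an estimated correlation in camera 0 passed (lowest adjusted p = 0.699), and 1 list had an unadjusted p under 0.05. With fry only cytokines and acute inflammation passed (adjusted p = 0.0148), and 5 lists had an unadjusted p under 0.05. For each list below, the preset p is given, and each of the 18 has an adjusted p = 0.699 with an estimated correlation.

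Inflammatory and immune lists passed upward. Among cytokines and acute inflammation, 7 of 11 tested members rose and none fell (camera adjusted p = 1.41e-06, 8 rose adjusted over the list alone). Examples are the iron-binding protein gene Lcn2 (2.49, SE 0.123), Cxcl15 (2.49, SE 0.158) and Ccl20 (1.55, SE 0.133). This list holds 22 members, and Il1b, Il6, Tnf, Cxcl1 and Ccl2 are among those not tested. The filter uses the mean over all libraries, so a gene can pass through a single genotype. Ccl20 did so, at 0.195 and 0.061 scaled FPKM in mice 27 and 28 and 2.21 and 2.36 in mice 26 and 29. In macrophages and myeloid cells 3 of 19 rose (camera adjusted p = 0.00173, 5 adjusted over the list alone), namely Cd14, Fcgr3 and Laptm5. Some members that did not pass were near 0, among them Csf1r (-0.02), Emr1 (0.05), Mrc1 (-0.20), Itgam (-0.14) and C1qa (0.14). Others that did not pass were higher, among them Fcer1g (0.70), Cx3cr1 (0.63), Ctss (0.61) and Cd68 (0.54). Of the 19, 15 lay above 0 and 4 below it (median 0.38). In interferon response 5 of 21 rose (camera adjusted p = 8.20e-04, 6 adjusted over the list alone), among them Oasl2, Rsad2, Irf7 and Zbp1. In MHC and antigen presentation 2 of 15 rose (camera adjusted p = 1.91e-05, 8 adjusted over the list alone), H2-K1 (0.92, SE 0.172) and H2-Ab1 (0.62, SE 0.117). In unfolded protein response 2 of 26 rose (camera adjusted p = 0.00787, 2 adjusted over the list alone), Edem1 (1.11, SE 0.141) and Trib3 (0.66, SE 0.123). Of the 33 ribosomal protein genes tested none passed singly by limma or adjusted over the list alone, and all 33 had values above 0 (median 0.37, camera adjusted p = 5.49e-05). The calls for macrophages and myeloid cells, unfolded protein response and ribosomal proteins were lost without mouse 28, and that for unfolded protein response also without mouse 26.

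**Figure D3:**
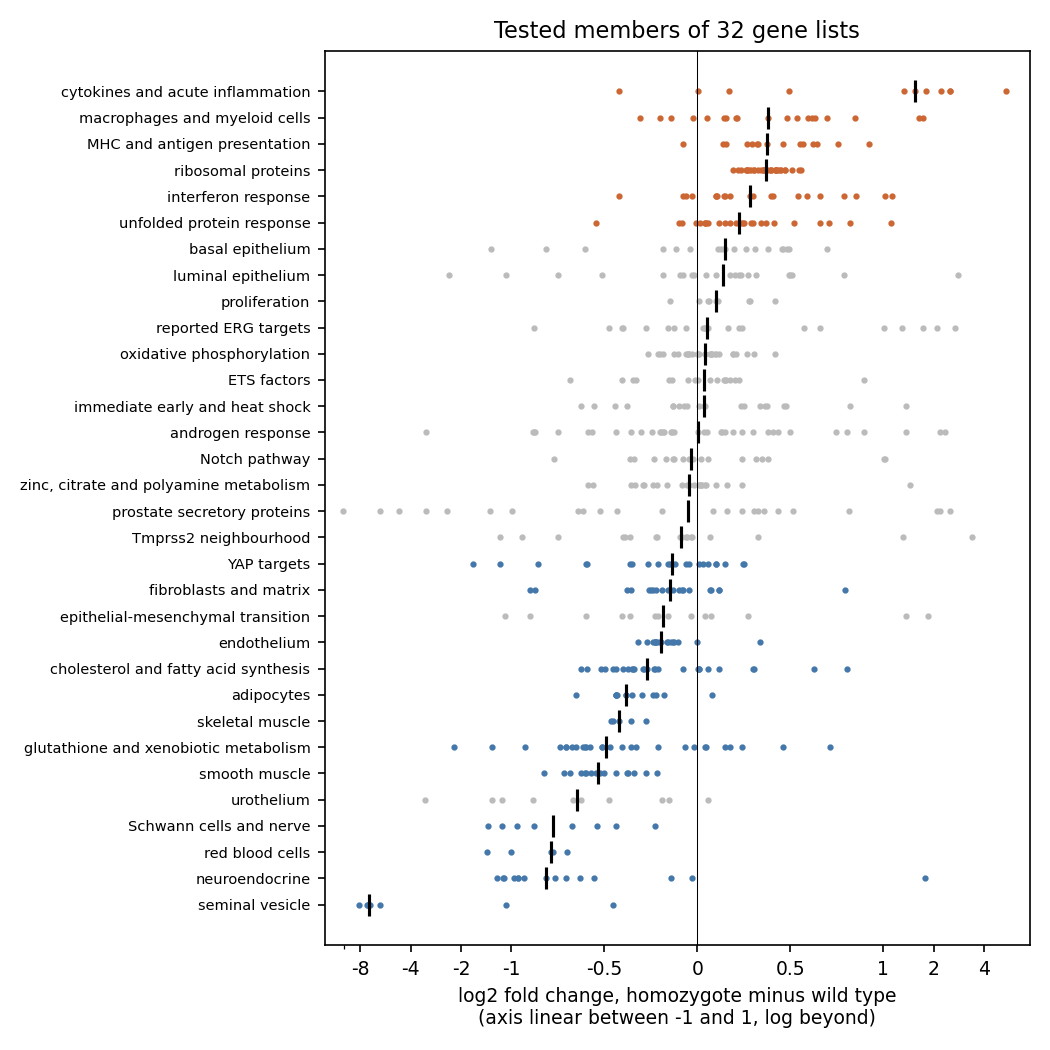
Log2 fold change (homozygote minus wild type) of the tested members of 32 gene lists, 1 point per gene, with a bar at each list's median. Orange lists passed camera upward, blue lists downward and grey lists did not pass at the preset correlation; the axis is linear between -1 and 1 and logarithmic beyond.

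Lists for seminal vesicle, stroma and metabolism were among those that passed downward. In seminal vesicle 6 of 9 fell (camera adjusted p = 5.51e-06, 8 adjusted over the list alone, median -7.07), the genes named above. The other tested members did not pass by limma: Ceacam10 (-6.12, SE 1.35, limma adjusted p = 0.0559), Pate4 (-1.08, limma adjusted p = 0.325) and Pax2 (-0.46, limma adjusted p = 0.186). Svs2, Svs4 and Svs5 hold the code and were not tested. Svs2 is at the code in all 4 libraries, and Svs4 and Svs5 are at the code in mouse 27. In mice 28, 26 and 29, Svs4 is at 2406, 193 and 305 FPKM and Svs5 at 20914, 6387 and 12211. In glutathione and xenobiotic metabolism 5 of 28 fell and 1 rose (camera adjusted p = 2.65e-04, 11 fell and 2 rose adjusted over the list alone). The secreted glutathione peroxidase gene Gpx3 fell by 2.19 (SE 0.173), from 1447 ± 73.5 to 316 ± 3.83 scaled FPKM (SD, n = 2 each), and Gstm5, Gsta3 and Txnrd1 fell by 0.71, 0.65 and 0.60. In smooth muscle 1 of 17 fell, Pgm5 (-0.72, SE 0.122), and all 17 had values below 0 (camera adjusted p = 8.18e-06, 1 adjusted over the list alone). In red blood cells 1 of 5 fell, Alas2 (camera adjusted p = 0.00220, 4 adjusted over the list alone). In neuroendocrine 1 of 15 fell, Ncam1 (-1.11, SE 0.219), and the calcitonin gene Calca rose by 1.78 (SE 0.128) (camera adjusted p = 0.0163, 3 fell and 1 rose adjusted over the list alone). YAP targets had 2 of 23 fall, Ctgf (-1.16, SE 0.171) and Ankrd1 (-1.71, SE 0.303) (camera adjusted p = 0.0396, 4 adjusted over the list alone). In fibroblasts and matrix 1 of 20 fell, Postn (-0.87, SE 0.114) (camera adjusted p = 0.0457, 1 adjusted over the list alone). In cholesterol and fatty acid synthesis 1 of 27 fell, Fdft1 (-0.52, SE 0.101) (camera adjusted p = 0.00787, 0 adjusted over the list alone). No single member passed, by limma or adjusted over the list alone, in Schwann cells and nerve (0 of 8, camera adjusted p = 0.0112), endothelium (0 of 17, camera adjusted p = 0.0184), adipocytes (0 of 13, camera adjusted p = 0.0250) or skeletal muscle (0 of 5, camera adjusted p = 0.0457). The calls for YAP targets, neuroendocrine, fibroblasts and matrix, endothelium, Schwann cells and nerve, and cholesterol and fatty acid synthesis were lost without mouse 28. Those for skeletal muscle and adipocytes were lost without mouse 27, those for YAP targets, endothelium and skeletal muscle without mouse 26, and those for fibroblasts and matrix and adipocytes without mouse 29.

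List calls also depended on processing. The robust trend setting also changed the list test, to one on the moderated statistics, and the effects of these changes were not separated. Under it, the calls for YAP targets, neuroendocrine, skeletal muscle, fibroblasts and matrix, endothelium, adipocytes, Schwann cells and nerve, unfolded protein response, and cholesterol and fatty acid synthesis were lost. Quantile normalization lost those for YAP targets, skeletal muscle and unfolded protein response. No filter on low values lost those for YAP targets and for fibroblasts and matrix, and a minimum mean of 5 those for fibroblasts and matrix and for endothelium. Leaving out genes that overlap another row lost that for neuroendocrine. Red blood cells and skeletal muscle had too few genes for a test without mouse 28, at a minimum mean of 5 and without overlapping genes, as had neuroendocrine and Schwann cells and nerve at a minimum mean of 5.

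Lists tied to the construct and to prostate epithelium did not pass at the main settings. Among reported ERG targets 6 of 22 rose and none fell (camera adjusted p = 0.0576, 7 rose and 3 fell adjusted over the list alone), among them the urokinase receptor gene Plaur (1.73, SE 0.106) and Pde3b (1.301, SE 0.110). That list passed without mouse 26, without mouse 29, with quantile normalization and with a robust trend. Of ETS factors 1 of 18 rose, Spdef (0.90, SE 0.106) (camera adjusted p = 0.766, 1 adjusted over the list alone). In the Tmprss2 neighbourhood 2 of 18 rose, Bace2 (3.41, SE 0.199) and Abcg1 (1.31, SE 0.116), and 2 fell, Tmprss2 itself and Fam3b (-1.17, SE 0.242) (camera adjusted p = 0.278, the same counts adjusted over the list alone). Of these, Abcg1 lies on chromosome 17 and is not local to Tmprss2 in the mouse. The call of Fam3b was lost with unscaled FPKM, quantile normalization, no filter and no trend, and without mouse 26 or mouse 29. In androgen response 3 of 37 rose and 3 fell (camera adjusted p = 0.938, 7 rose and 6 fell adjusted over the list alone): Azgp1 fell by 3.26 (SE 0.138) and Steap4 rose by 2.34 (SE 0.128). Its median was 0.005 and its test pointed down. In luminal epithelium 2 of 22 rose and 2 fell (camera adjusted p = 0.490, 4 rose and 3 fell adjusted over the list alone), with Ly6a at 2.80 (SE 0.179) and Psca at -2.37 (SE 0.185). In prostate secretory proteins 2 of 24 rose and 5 fell (camera adjusted p = 0.175, 4 rose and 7 fell adjusted over the list alone). In basal epithelium 1 of 19 rose, Itga6 (camera adjusted p = 0.223, 1 rose and 1 fell adjusted over the list alone). In the Notch pathway 1 of 18 rose, Notch4 (camera adjusted p = 0.794, 2 adjusted over the list alone), with a median of -0.04 and a test that pointed up. In epithelial-mesenchymal transition 2 of 14 rose, Tgfb1 (1.85, SE 0.142) and Twist2 (1.36, SE 0.127), and 1 fell (camera adjusted p = 0.354, 2 rose and 3 fell adjusted over the list alone). In immediate early and heat shock 2 of 21 rose, Nr4a1 and Egr1, and 1 fell (camera adjusted p = 0.354, the same counts adjusted over the list alone). In urothelium 1 of 10 fell, Gsdmc2 (camera adjusted p = 0.0840, 1 adjusted over the list alone). No member passed, by limma or adjusted over the list alone, in proliferation (0 of 9, camera adjusted p = 0.223), zinc, citrate and polyamine metabolism (0 of 24, camera adjusted p = 0.209) or oxidative phosphorylation (0 of 29, camera adjusted p = 0.876). Lymphocytes (2 tested genes) and epididymis and vas deferens (4) had too few genes for a list test, and no member passed over all genes tested, while 1 lymphocyte gene rose adjusted over the list alone. Besides reported ERG targets, 6 of these lists passed under some alternative, each in the direction of its main test. Prostate secretory proteins passed downward without mouse 28 (camera adjusted p = 0.00762), without mouse 26 and with a robust trend. Urothelium passed downward with unscaled FPKM, without mouse 27 (camera adjusted p = 5.24e-06) and without mouse 29. Basal epithelium passed upward without mouse 28 (camera adjusted p = 2.28e-05), the Tmprss2 neighbourhood downward at a minimum mean of 5 (camera adjusted p = 0.0421), proliferation upward without a filter (camera adjusted p = 5.23e-04), and zinc, citrate and polyamine metabolism downward with quantile normalization (camera adjusted p = 0.0463).

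Among single members named from the lists, the limma calls of Ctgf, Ankrd1, Itga6, Ncam1, Pgm5, Postn, Alas2, Laptm5, H2-K1, H2-Ab1, Oasl2, Irf7, Egr1, Trib3, Fdft1, Gstm5, Gsta3 and Txnrd1 were lost both without mouse 26 and without mouse 29. Those of Spdef, Rsad2 and Edem1 were lost without mouse 26 only, and that of Notch4 without mouse 29 only, among the libraries left out. Without a filter on low values, the calls of Ctgf, Ankrd1, Itga6, Ncam1, Gsdmc2, Alas2, H2-K1, H2-Ab1, Rsad2, Irf7, Zbp1, Egr1, Trib3 and Fdft1 were lost. Unscaled FPKM lost those of Itga6, Ncam1, Alas2, Fdft1 and Txnrd1, and quantile normalization those of Ankrd1, Itga6, Alas2, H2-K1 and H2-Ab1. Fits without a trend lost those of Itga6, Alas2 and Fdft1, a robust trend that of Gsdmc2, and the authors' deposited call that of Fdft1.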

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

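The setting that kept the coded top value and those leaving out genes listed at 0 or overlapping genes were chosen after the data were seen. The number of called genes (900) stayed within 1.5 times under the scaling, pseudocount, filter and prior alternatives, but the authors' deposited call gave 2034, with 1012 higher, 1020 lower and 2 at a fold of 0, both with the coded top value in each library. Leaving out 1 library gave 355 to 2028 calls, 216 to 995 higher and 139 to 1033 lower. These fits have fewer libraries and take their spread only from the genotype that keeps 2, whereas the main fit pools both genotypes. The median absolute log2 difference was 0.106 between homozygotes and 0.183 between wild types. Calls rose in number without a wild type and fell without a homozygote. Any further cause was not tested. The number lower (353) was 185 with unscaled FPKM and 231 at a minimum mean of 5, which tests fewer genes. Without scaling, the median log2 fold over all tested genes was 0.0631, against -0.00327 with it. That is an upward shift, and whether it accounts for the fewer falls was not tested. The number of called lists (18) was 11 with a robust trend, where the cause was not tested, 1 with fry and 0 with an estimated correlation, and 9 to 18 with a library left out, where the 9 (without mouse 28) are of 30 lists tested. Tmprss2 fell by 0.67 with unscaled FPKM (adjusted p = 0.0597) and changed by -0.83 to -0.66 with a library left out. Of the called genes and lists followed through the alternatives, only Txnrd2 changed direction, with 0.0207 in the authors' deposited call. Leng1 was not followed through them. It fell by 2.38 in the main fit (limma adjusted p = 5.34e-04), but the authors' deposited table gives it a log2 fold of 0.668 with a q-value of 0.00396. The calls of Meg3 and Mirg were lost without a filter, and that of Meg3 with a robust trend. At 2 mice per genotype, 69% of simulated changes of 1 on the log2 scale were recovered, so smaller changes can be missed. Counting error per gene was not available from FPKM values.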

Other observations

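The mast cell and imprinted gene lists, and the tests below except those on overlapping genes, gene pairs within 1 Mb and the unseen imprinted genes, were chosen after the values they concern were seen. Of 12 tested mast cell genes 9 rose in homozygotes and none fell (median log2 fold change 2.31, camera p = 1.78e-14 at the preset correlation, p = 0.0711 with an estimated correlation, limma calls). The list holds 21 members and was made after Tpsab1 and other members had been seen, so its count is not independent evidence. Some risen members, such as Mcpt2, Il1rl1 and Fcer1a, passed the filter only through the homozygotes, which tilts the count upward. Fcer1a, for example, was at 0.132 and 0.130 scaled FPKM in mice 27 and 28. The tryptase gene Tpsb2 rose by 4.23 (SE 0.141), the carboxypeptidase gene Cpa3 by 3.48 (SE 0.127), the chymase gene Cma1 by 3.63 (SE 0.179) and the IgE receptor gene Fcer1a by 1.62 (SE 0.181). Kit was at 2.46 and 3.28 scaled FPKM in wild types and 3.99 and 4.32 in homozygotes, and did not pass (adjusted p = 0.170). Slc18a2 (0.23) and Gata2 (-0.08) did not pass either.

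In the first pattern, 6 seminal vesicle genes and Spink3 were lower and other genes higher in homozygotes; carry-over of seminal vesicle into the wild-type dissections would give its genes 1 ratio between mice 27 and 28. Over all 9 tested members they did not (SD of the log2 ratio 1.92, median 4.37), and this was the criterion first written. Svs2, Svs4 and Svs5 hold the code in mouse 27 and give no ratio, so they count on neither side. Pate4 was still at 4318 and 8148 scaled FPKM in mice 26 and 29. Pax2 was at 2.78 and 3.22 in mice 27 and 28 and at 1.57 and 2.30 in mice 26 and 29. Genes also present in homozygotes need not share the ratio even under carry-over, so the first criterion cannot decide for the list as a whole. A version rewritten with the values in view, over the 6 called members, gave an SD of 0.401 (median 4.55), but it leaves out Pate4 (0.68) and Pax2 (-0.21), which break that ratio, and Ceacam10 (4.51), which shares it, so it decides nothing and carry-over stays open for the 7 that share it. Less ventral lobe tissue in the homozygotes cannot be told apart from a genotype effect: Sbp and Sbpl differed by 0.0196 in log2 ratio between mice 26 and 29, which near-identical genes that share reads would give in any case, and Spink3 differed from them by 1.46 in a single pair of libraries. For loss of a lobe as the whole cause of the rises, Pbsn, Msmb and Defb50 were the reference, taken as dorsolateral secretory genes. A share of 0.130 of the risen genes lay above the highest of them. Their own log2 fold changes were 0.24, 2.19 and 0.32, so they set no common ceiling, and that share leaves out their spread. By the rewritten version 19 genes rose beyond those genes' spread, between the limits of 5 and 20 set for it. Neither version decides the cause of the rises as a whole, although those 19 rose by more than each reference gene.

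Genes listed at 0 in both libraries of a genotype and at 3 or more scaled FPKM in both of the other form the second pattern, 8 genes in all. Of these, 6 overlap another row (odds ratio 14.8 against the other tested genes, Fisher's exact p = 4.76e-04), and for 5 of the 6 the fold in the authors' deposited table is within 1 of 0, so failed estimates at overlapping genes may account for those 5. That account does not extend to 9930021D14Rik, which overlaps a row but has an authors' log2 fold of 3.26, or to G6pc2 and Mcpt2, which overlap no other row. Mcpt2 (3.07, SE 0.114) is among the mast cell genes that rose. Txnrd2, for example, is at 7.93 and 9.03 FPKM in mice 27 and 28 and listed at 0 in both homozygotes, with an authors' log2 fold of 0.02. Atp6v1c2, Leng1 and Gt(ROSA)26Sor, also among the 5, are called in the authors' deposited table (q-values 0.0183, 0.00396 and 1.34e-04). For Leng1 the authors' log2 fold is in the opposite direction, at 0.668. A test for a chromosome interval of another strain by close pairs decides nothing. With 0 pairs within 1 Mb among the 8 genes, its share of random draws is fixed at 1. The genes at 0 lie on 4 chromosomes in each genotype, which a single interval could not hold if all 8 zeros were real. With the 5 possible failed estimates set aside, only G6pc2 remains at 0 in homozygotes, so the count cannot exclude a single interval there. In wild types 9930021D14Rik (chromosome 17) and Mcpt2 (chromosome 14) remain. Several intervals stay open. Neither test covers genes above 0, such as Gm5325, Gm5326, Abpd and Abpb on chromosome 7. These start at 31375592, 32441541, 33364343 and 34011932, with log2 fold changes of 6.53, 5.14, 6.04 and -6.43. Abpd lies within 1 Mb of both Gm5326 and Abpb. Whether these genes share an interval of another strain was not tested.

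The imprinted genes Dlk1, Rian, Meg3 and H19 rose together, which is the third pattern. As a group, the other 26 tested imprinted genes did not rise. Their median log2 fold change of -0.03 lay at percentile 44.2 of 10000 matched random lists, so a rise of imprinted genes in general is argued against. Of these 26, 2 rose, Rtl1 (2.19, SE 0.128) and Mirg (1.59, SE 0.244), both on chromosome 12 with Dlk1, and 3 fell. Igf2, on chromosome 7 with H19, was higher by 0.72 (SE 0.155) and did not pass (limma adjusted p = 0.0533). Of the 4 organ and tissue lists that could be tested, none passed upward, and the highest median was -0.38. That argues against tissue of another organ for urothelium, adipocytes and skeletal muscle, the last with 5 of 17 members tested. The seminal vesicle list (median -7.07) cannot decide this, because its genes were so much higher in wild types. Tissue of another organ stays open for epididymis and vas deferens, which had too few genes, and for organs without a list. A local effect at the Dlk1 region, which would leave out H19 on chromosome 7, a change in cell types and a strain difference remain untested.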
